A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

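The data were 4 two-colour Agilent tiling arrays of Schizosaccharomyces pombe, all on the same slide. Per the labels' protocols, RNA was reverse transcribed with an anchored oligo(dT) primer, and the cDNA of wild type or the OFF state was labelled with Cy3 and that of the mutant or the ON state with Cy5. The groups were the deletion of rnh1 and rnh201 over wild type, and rnh1 ON over OFF, with 2 arrays each.

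The scanner output of each array was made with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. Per the file headers and columns, it gives raw median signal intensity and local background intensity per spot and dye, processed signal intensity after background subtraction and dye normalization, a log10 ratio of Cy5 over Cy3, a p-value of that ratio from Agilent's error model, and flags for each spot. The deposited value table of the series holds log2 ratios. Against the scanner values, it equalled Agilent's log10 ratio converted to log2 wherever it was not 0, within 0.139, and it was 0 exactly where Agilent's p-value was 0.05 or more. Those zeros made up 63.5% to 85.2% of tiling probes per array, so that the median of every column was 0. Its scale, centring and direction were therefore settled by this comparison.

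Each array had 180880 spots, including 3440 control spots, 174063 tiling probes, 300 probes spotted 6 times, 150 random-sequence probes by their names, and 1427 further probes of another name series. The median raw signal of the tiling probes was 259.5 to 328 in Cy3 and 168 to 304 in Cy5, with median backgrounds of 51 to 55 and 55 to 59. Non-uniformity or population outlier flags marked 16.5% to 20.7% of tiling probes per array.

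Background was corrected by normexp with an offset of 50 on the median foreground and median background signals, because the files hold no mean foreground signal, which had been planned. Log2 ratios were normalised by loess within each array, with control spots at weight 0. Tiling probes flagged on any array were left out (45539), as were those not well above background in at least 1 channel on at least 2 arrays (50785), leaving 77739. A linear model with a coefficient for each comparison was fitted in limma 3.58.1 under R 4.3.3, and its variances were moderated by eBayes (2 residual degrees of freedom, 6.18 prior degrees of freedom, prior SD 0.231). Each coefficient and their difference were tested two-sided against 0 and adjusted by Benjamini-Hochberg, with a threshold of 0.05. Files were read with data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9.

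The tests had been planned per gene, falling back to probes if probes could not be placed. The reference used here pairs gene names with locus tags and not with probes, and neither probe sequences nor positions were used. Tests of gene lists, of rnh1 and rnh201 by name, of antisense and intergenic transcription, and the planned rule for naming genes were therefore not run. Runs of probes and the rule for naming them, the runs with the largest mean log2 ratio in each direction, were chosen after the data were seen. Probe numbers were not converted to genome positions. Runs, comparisons of nearest probes and shifts did treat probes of one parity with nearby numbers as neighbours, which was not checked against the genome.

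The fit was tested on simulated data with the variance model of these arrays. With 200 of 77739 probes changed, none was recovered at a log2 change of 0.5 or 1, and 99.0% (deletion) and 99.5% (induction) were recovered at 2. With 10000 changed, 94.7% and 94.2% were recovered at a log2 change of 1, where 4.36% and 4.14% of calls were false. At a log2 change of 0.5, 0% of the 10000 were recovered in either simulated comparison. The simulated noise was independent between probes and arrays and held no dye effect. These shares of false calls therefore need not hold for the real arrays.

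Alternatives covered background correction, normalization, the value table, the filter, the arrays in the fit, the variance model, thresholds, arrays left out in turn, and a replicate block. The alternative without background subtraction likewise used median signals. All 4 arrays shared a slide, so no slide effect could be fitted.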

Results

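Gene expression was compared in fission yeast (Schizosaccharomyces pombe) with altered levels of RNase H, the enzyme class that degrades the RNA strand of RNA-DNA hybrids. The rnh1 gene encodes RNase H1 and rnh201 encodes the catalytic subunit of RNase H2. Labelled cDNA, made from RNA with an oligo(dT) primer, was hybridised to 4 arrays that tile the genome, each with 2 dyes. On 2 arrays, a strain lacking both rnh1 and rnh201 was labelled with Cy5 and wild type with Cy3, both grown in rich medium. On the other 2 arrays, a strain with rnh1 under an nmt promoter, which thiamine represses, was compared with itself. Cells without thiamine (ON) were labelled with Cy5 and cells with thiamine (OFF) with Cy3. The design text calls the 2 arrays of each comparison biological replicates. A positive log2 ratio means a higher signal in the deletion strain or in the ON state. The dyes were not swapped, and removal of thiamine cannot be separated from induction of rnh1.

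Each array carried 174063 tiling probes. In the Cy3 channel, 60.2% to 68.3% of them were well above background, and in the Cy5 channel 58.4% to 68.6%. No tiling probe was saturated. The median SD of the log2 ratio among 6 spots of the same probe was 0.13 to 0.14. Log2 ratios correlated across probes at r = 0.752 between the 2 deletion arrays and at r = 0.682 between the 2 induction arrays, probes not being independent replicates. After filtering, 77739 probes were tested. The files used here pair no probe with a gene, strand or position, so results are given for probes and for runs of probes, and no gene is named from them. The number of arrays, 2 per comparison, limits the precision of every value.

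Probes with even and odd numbers behaved as separate interleaved series. The log2 Cy3 signals of probes 2 numbers apart correlated at r = 0.799 to 0.805, while those of adjacent numbers correlated at r = -0.503 to -0.487. Ratios of probes 2 numbers apart correlated at r = 0.527 to 0.705. A run was therefore defined, after the data were seen, as at least 5 called probes of one parity that changed in one direction with at most 1 uncalled probe between neighbours. The runs named were, in each direction, those with the largest mean log2 ratios, and each is identified by its first probe.

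The first comparison asked how the transcriptome differs when both RNase H genes are missing. In the deletion strain, 14497 probes rose and 7962 fell relative to wild type, together 28.9% of the probes tested (limma, Benjamini-Hochberg adjusted p under 0.05). The median log2 ratio was 0.81 among the probes that rose and -0.65 among those that fell. Changes of at least 2-fold were mostly upward, with 4614 probes higher and 568 lower. With Agilent's log ratios there were 7559 higher and 4813 lower. The higher probes included 656 runs holding 6584 probes, against at most 62 runs in 100 shuffles of the calls among tested probes of the same parity. The lower probes included 220 runs holding 1764 probes, against at most 10 in the shuffles. Shuffling removes the correlation between neighbours of the same parity that led to the run definition. Fewer shuffled runs therefore had to follow, and they do not show that the runs are changes in expression. Without deletion replicate 2 there were 389 runs of higher and 50 of lower probes.

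The highest run, of 5 probes starting at sp40c_49240, had a mean log2 ratio of 3.73 ± 0.33 (SD, n = 2 arrays), and its limma adjusted p-values did not exceed 9.45e-05. The second, of 5 probes starting at sp40c_120274, averaged 3.15 ± 0.08 (SD, n = 2 arrays). The lowest run, of 14 probes starting at sp40c_69214, averaged -4.68 ± 0.06 (SD, n = 2 arrays), and its limma adjusted p-values did not exceed 4.73e-05. For 4 of these 14 probes the deletion strain was not well above background on either array, and wild type was at least 8.04-fold to 22.5-fold brighter. The mean of this run was -5.96 to -4.64 over the alternatives. Such bounds set the brighter channel against the lowest signal well above background in the dimmer one, and are open to dye bias. The next lowest run, starting at sp40c_53385, had 18 called probes and averaged -1.97 ± 0.09 (SD, n = 2 arrays), and 12 of its probes had only a bound, at least 1.43-fold to 5.27-fold. Its mean depended on the processing and ranged from -3.60 to -1.91 over the alternatives.

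The count of changed probes depended on deletion replicate 2. It was 12139 of the 51526 probes well above background in both channels on all 4 arrays, against 22459 of 77739 tested. With Agilent's processed signals centred on the array median, 49.1% of the called probes were higher, against 64.5%.

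The second comparison asked what changes when rnh1 is induced. In the ON state, 3777 probes rose and 1671 fell relative to OFF, together 7.01% of those tested (limma, Benjamini-Hochberg adjusted p under 0.05). The median log2 ratio was 0.95 among the probes that rose and -0.82 among those that fell, and 1672 rose and 467 fell by at least 2-fold. The higher probes included 116 runs holding 1042 probes, and the lower probes 49 runs holding 388 probes. Shuffled calls gave at most 1 run of higher probes and 0 runs of lower probes, which again had to follow from removing the correlation between neighbours. Without ON replicate 2 there were 69 runs of higher and 19 of lower probes, and without ON replicate 1 there were 27 of lower probes. Leaving out 1 deletion array, whichever it was, gave 275 and 127. Median centring gave 137 and 190 runs, with all tested probes shifted downward to a median log2 ratio of -0.10.

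The highest run, of 5 called probes starting at sp40c_99011, had a mean log2 ratio of 9.55 ± 0.007 (SD, n = 2 arrays), with limma adjusted p-values of 4.23e-08. The mean was 9.28 to 11.77 over the alternatives, so the SD between arrays understates its uncertainty. For 4 of its probes the OFF state was not well above background, and the ON state was at least 544-fold to 708-fold brighter. None of its probes was called in the deletion comparison, where they averaged -0.17. The second run, of 16 probes starting at sp40c_69208, averaged 4.78 ± 0.26 (SD, n = 2 arrays). The lowest run, with 7 called probes starting at sp40c_3199, averaged -2.07 ± 0.09 (SD, n = 2 arrays), and its 7 probes were also called lower in the deletion strain, at -1.26. The next lowest, with 17 called probes starting at sp40c_2600, averaged -1.90 ± 0.02 (SD, n = 2 arrays), whereas its mean in the deletion strain was 0.62, with 11 probes called. For 4 of its probes the ON state was not well above background, with OFF at least 2.72-fold to 3.75-fold brighter, and the mean was -2.80 to -1.89 over the alternatives.

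The direction of this comparison depended on the normalization. The share of called probes that were higher was 69.3% after loess, but 37.3% after median centring, where the median log2 ratio of all tested probes was -0.10 against 0.002 after loess, 46.9% with Agilent's log ratios and 34.1% with Agilent's processed signals centred on the median, where that median was -0.12. The count was 3164 without ON replicate 2, and 11900 with 1 deletion array left out, whichever it was, when only the induction arrays estimated the spread.

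The run starting at sp40c_69208 overlapped the lowest run of the deletion comparison. Of 17 probes that fell by at least 2-fold in the deletion strain and rose by at least 2-fold in the ON state, 14 lay in this stretch. In it, 13 even-numbered probes averaged -4.70 ± 0.05 in the deletion strain and 4.80 ± 0.26 in the ON state (SD, n = 2 arrays). The 3 even-numbered probes just before them rose in the ON state, at 4.70 ± 0.27, and were not called in the deletion strain, at -0.04 ± 0.15. Among the odd-numbered probes lying between the 13, 7 were tested, and all 7 fell in the deletion strain, averaging -1.79 ± 0.04, while 2 of them rose in the ON state. Nearby probes also changed in other ways. The last probe of the deletion run fell in the deletion strain, at -4.44, and was at 0.04 in the ON state. Odd-numbered probes at both ends of the run rose in the deletion strain, at 1.69, 1.37 and 2.72. So did the even-numbered sp40c_69194, sp40c_69196 and sp40c_69202 before it, at 1.57, 1.63 and 2.28. The odd-numbered probes sp40c_69197 to sp40c_69207 before the run fell in the deletion strain, averaging -0.91, and averaged 0.64 in the ON state.

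**Figure D1:**
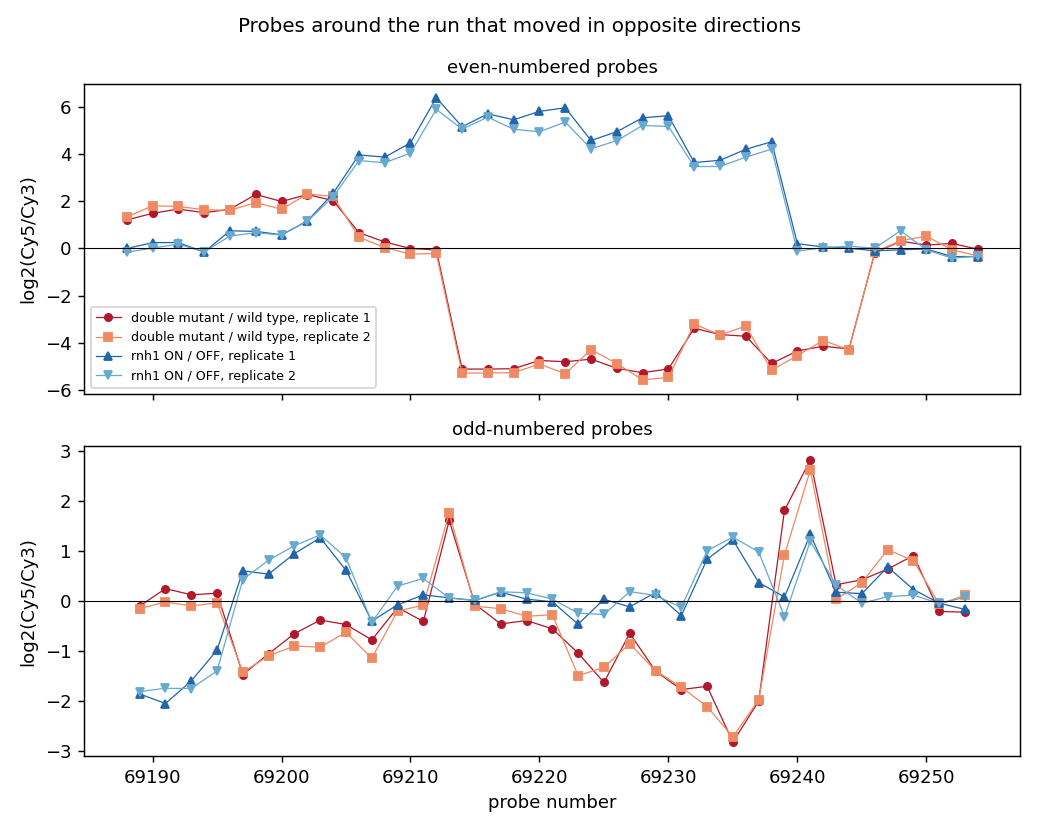
Normalised log2(Cy5/Cy3) of each array (points, joined by lines) against probe number, with even-numbered probes above and odd-numbered probes below, including probes that were not tested. In the even-numbered series 13 probes averaged -4.70 in the deletion strain and 4.80 in the ON state.

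Across the 77739 tested probes, mean log2 ratios of the comparisons correlated positively (Pearson r = 0.381, Spearman rho = 0.442). Single arrays of the 2 comparisons correlated at r = 0.351 and 0.464 with the same replicate number and at 0.209 and 0.276 otherwise. These were below the values within each comparison. Probes called higher in both numbered 2436, where independent lists of these sizes would share 704.3, and probes called lower in both numbered 650, against 171.1. Opposite calls were fewer than for independent lists. There were 252 probes higher in the deletion strain and lower in the ON state, against 311.6, and 80 lower in the deletion strain and higher in the ON state, against 386.8. Both comparisons had the same dye orientation, so a dye effect of each probe would enter both. The calls of a probe also rest on a shared estimate of its spread, so the lists are not independent by construction.

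**Figure D2:**
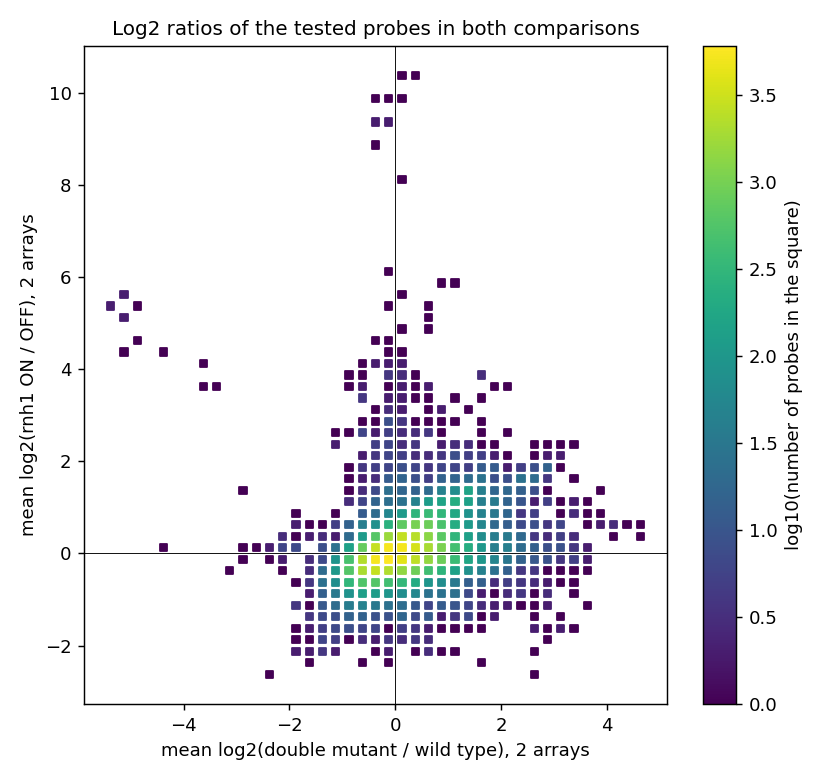
Mean log2 ratio in the deletion comparison (x axis, 2 arrays) against that in the induction comparison (y axis, 2 arrays) for the tested probes, with colour for the log10 number of probes per square. The correlation is 0.381, and the isolated group at upper left holds probes of the stretch at sp40c_69214.

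The difference between the comparisons, in which a dye effect common to all arrays cancels, was called for 4758 probes (limma, Benjamini-Hochberg adjusted p under 0.05). The ratio was higher in the deletion comparison for 3895 of them and lower for 863. Of the probes called in the deletion comparison, 24.7% of the higher and 5.38% of the lower ones were also called, in the same direction, in this difference. For the induction comparison these shares were 13.0% of the higher and 29.9% of the lower probes. The difference has a larger standard error than either comparison, so a probe missing from it is not shown to be free of change. All probes of the lowest deletion run and of the highest induction run were called in the difference. The count of 4758 was larger without deletion replicate 1. It was 1606 of the 51526 probes well above background in both channels on all 4 arrays.

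Called probes were unevenly spread along the probe numbers. The following values are for the 174 of 175 stretches with at least 100 tested probes. In the deletion comparison, the median stretch of 1000 numbers had 17.5% of its tested probes called higher, and the stretch starting at 114001 had 64.4%. The corresponding values for lower probes were 8.93% and 45.2%, the latter in the stretch starting at 141001. In the induction comparison, the stretch starting at 114001 again had the largest share called higher, 24.8% against a median of 3.93%. The last stretch, which was left out, had only 39 tested probes, with 12 called higher in the ON state (30.8%). Lower probes were most frequent in the stretch starting at 2001, at 21.0% against a median of 1.49%.

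**Figure D3:**
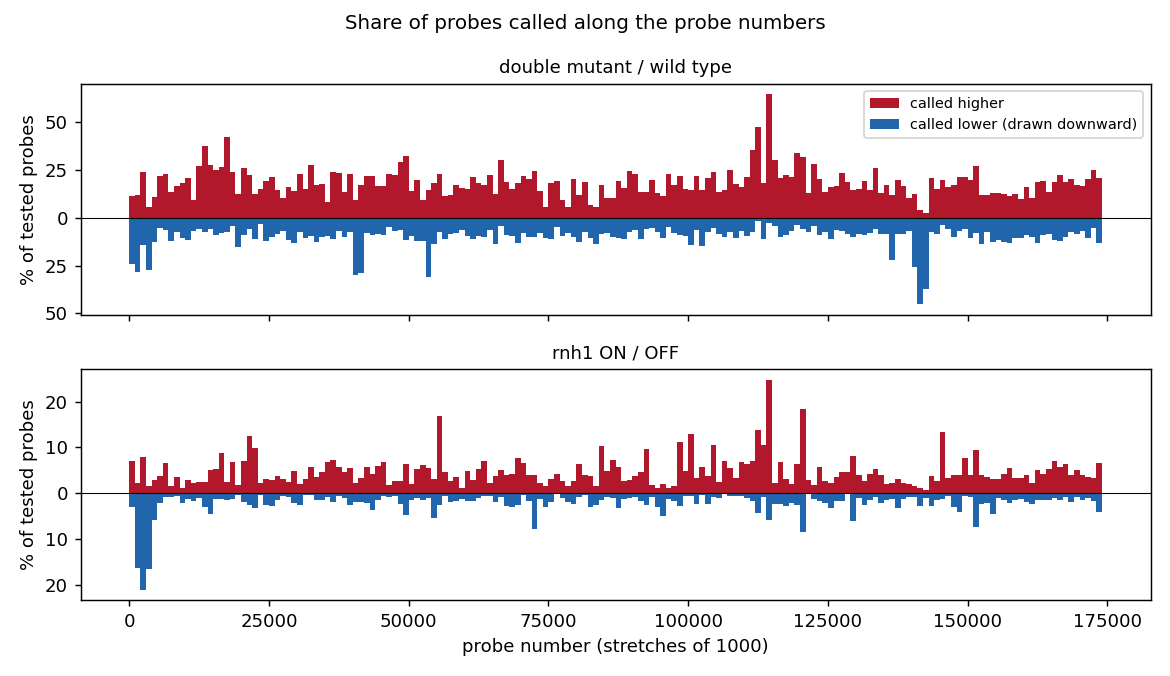
Percentage of tested probes called higher (red, upward) and lower (blue, downward) in each stretch of 1000 probe numbers, for the deletion comparison (top) and the induction comparison (bottom), with different vertical scales and without the last stretch of 39 tested probes. Among the stretches drawn, the highest share called higher is 64.4% in the deletion comparison and 24.8% in the induction comparison, both in the stretch starting at 114001.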

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

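The probes in this part were outside the comparisons, and the neighbour tests were chosen after the results were seen. Among the random-sequence probes, 13 passed the filter, and these drew calls, made at the p-value limit of the tiling probes, although they were not designed as tiling probes. In the deletion comparison 8 (61.5%) were called, against 28.9% of tiling probes, and in the induction comparison 3 (23.1%), against 7.01%. All of them were lower, so a lower call can occur in a probe not designed as a tiling probe. Random-sequence probes were well above background more often in Cy3 (8.67% to 9.33%) than in Cy5 (2.67% to 5.33%). The filter accepts a probe through 1 channel, which here favours lower ratios. Their direction and share of calls may therefore follow from the filter. Of the 69 passing probes of the other name series, 37 (53.6%) were called in the deletion comparison, 2 of them higher. In the induction comparison 12 (17.4%) were called, 0 of them higher. In the difference between the comparisons, limma called 0 of the 13 random-sequence probes, 1 having an unadjusted p under 0.05, and 1 of the 69 others, 7 having an unadjusted p under 0.05. Of the tiling probes only 6.12% were called in the difference, so few calls among 13 probes carry no weight.

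Calls in the same direction in both comparisons were more frequent than for independent lists, with 2436 probes higher and 650 lower. A candidate explanation is a dye effect set by each probe's own sequence. It would leave neighbouring probes unmoved if their sequences were unlike. The nearest probes of the same parity moved 0.466 times as far as the probes called higher in both (95% bootstrap interval 0.442 to 0.487), and 0.380 times as far as those called lower in both (0.322 to 0.425). These neighbours included dim and flagged probes left out of the tests, and the called probes were selected as called. Both can lower the values. The bootstrap treated probes as independent, although many lie in runs, so the intervals are likely too narrow. The neighbours did move, which argues against such an effect as the only cause for these probes. Both values lie between the limits set for the test, so a partial dye effect and a response shared by both comparisons cannot be told apart. With the dyes never swapped, the design keeps this open.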

How the results depend on the processing

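Keeping flagged spots and counting only probes in runs were alternatives chosen after the data were seen. Of 22459, 5448 and 4758 probes called in the deletion comparison, the induction comparison and their difference, the value table gave 8208 and 1013 for the comparisons. A filter on both channels on all 4 arrays, which left 51526 probes tested, gave 12139 for the deletion and 1606 for the difference. Requiring a log2 ratio of at least 1 gave 5182 and 2139. An adjusted p of 0.01 gave 8669, 1455 and 1617, and one of 0.1 gave 9685 for induction and 8243 for the difference. For induction, Agilent's log ratios gave 2629, Agilent's centred processed signals 3601, median centring 10377, and the 2 induction arrays alone 11900. Requiring a call in the difference, in which a common dye effect cancels, as well as in the comparison itself left 4011 and 990. Keeping flagged spots gave 3004 of 123246 tested for induction, and counting only probes in runs gave 8348, 1430 and 1970. Leaving out 1 array gave 13454 to 21686, 3164 to 11900, and 3432 to 7992, the lone array being assumed to vary like the others. Beyond the stricter filters and thresholds, the cause was not tested.

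The share called higher was 64.5%, 69.3% and 81.9%. It was 49.1% for the deletion and 34.1% for induction with Agilent's centred processed signals, where the median of tested probes was -0.10 and -0.12. For induction it was 46.9% with Agilent's log ratios and 37.3% with median centring, and for the difference 57.3% with the value table. A replicate block gave 56.5% for induction and 64.4% for the difference, and requiring a call in the difference gave 89.3% for the deletion and 49.6% for induction. For the deletion, an adjusted p of 0.01 gave 79.1% and a log2 ratio of at least 1 gave 89.0%. The correlation between comparisons, 0.381, was 0.271 with the value table, 0.294 to 0.402 with 1 array left out. Under the 6 settings that change the log2 ratios themselves, 33 of 48 means of named runs moved by more than 1 SD between arrays, and 0 changed sign. Runs in the deletion comparison, 656 higher and 220 lower, numbered 137 and 17 with the value table and 1130 and 687 with a replicate block. In the induction comparison, 116 and 49 became 6 and 0 with the value table and 488 and 285 with the block.

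With a replicate block, which leaves 1 residual degree of freedom, 42378, 23352 and 20310 probes were called. Deviations of same-numbered arrays correlated at 0.606, but 2 pairs do not establish that the numbers pair the arrays. No spot was saturated, so leaving out saturated probes tested nothing. Alternatives on gene summaries, gene lists, thiamine genes and antisense or intergenic probes were not run, for want of gene links. Dim probes limit the ratios, among them those of named runs in which some probes had only a bound.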

Other observations

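The tests of a common dye effect, and those of dim probes and of background correction separately, were chosen after the results were seen. Runs in the comparisons overlapped unevenly. Of 116 runs higher in the ON state, 67 had 50% or more of their tested probes called higher in the deletion strain too. Of 49 runs lower in the ON state, 12 had as large a share called higher in the deletion strain, and 11 had as large a share called lower there. Of 656 runs higher in the deletion strain, 393 had no probe called in the induction comparison. With 28.9% of tested probes called in the deletion comparison and 7.01% in the induction comparison, such shares are bound to differ. The longest run of higher probes in the deletion strain had 112 called probes, and the longest of lower probes 37.

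In the stretch at sp40c_69214, 13 even-numbered probes fell in the deletion strain and rose in the ON state. The mean of the run in the deletion strain was -5.96 to -4.64 under the alternatives, the lowest with Agilent's centred processed signals. A hypothesis is that the run lies in the targeted gene, so loss and induction both act on it, which here would be rnh1. Such a run appeared in 4 of 100 circular shifts of one comparison against the other, within the limit of 5 set beforehand but close to it. The run definition itself was chosen after the data were seen. Shifts ask only whether opposite calls coincide more than in misaligned comparisons. They cannot tell which gene the run lies in. The 3 even-numbered probes just before it, which rose to 4.70 in the ON state and averaged -0.04 in the deletion strain, could mark transcript outside the deleted part. The last probe of the run fell in the deletion strain but was at 0.04 in the ON state. The untested sp40c_69242 after it was alike, at -4.15 and -3.91 on the deletion arrays and 0.06 and 0.02 on the induction arrays. Nearby probes rose in the deletion strain, at up to 2.72. Of the odd-numbered probes before the run, sp40c_69189 to sp40c_69195 fell in the ON state. Those nearer to it, sp40c_69197 to sp40c_69207, moved in opposite directions as the run did. They averaged -0.91 in the deletion strain and 0.64 in the ON state, where 4 of 6 were called higher. The hypothesis alone does not account for all of these neighbours. Whether they count against it cannot be said without the positions of the deletion and the promoter, so the run's identity stays open.

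Among changes of at least 2-fold in the deletion strain, 89.0% were upward. Dim probes alone do not account for this, since 87.5% were upward among probes well above background in both channels on all 4 arrays, a filter that keeps the background correction and so, contrary to the test as first written, does not bear on it. Among the 2534 also called in the difference between comparisons, where a dye effect common to all 4 arrays cancels, 93.3% were upward. These were still selected on the deletion ratio, which holds such an effect, so this share does not exclude it. Changed alone, background correction left 87.3% upward without subtraction and 83.6% with a smaller offset, and median centring left 81.0%. Agilent's log ratios, which change background correction and normalization together, gave 61.1%. So these 2 steps, a common dye effect and a biological excess cannot be told apart. The genotype stays among the open explanations, untested.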
